A study of Mus musculus with 12 samples.

How the data were processed

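Messenger RNA levels were measured in macrophages sorted from normal mouse pancreas and from pancreatic tumor tissue, on 12 single-color arrays of an Agilent mouse design with 4 arrays to a slide, 6 arrays per group. Per the labels' protocols, sorted cells went directly into lysis buffer, total RNA was extracted, and cDNA was amplified with a whole-transcriptome kit and labelled chemically with Cy5. Amplification can change the balance between transcripts, so a fold here is a fold of amplified signal.

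Per the file headers, each array was read in the red channel alone with Agilent Feature Extraction 11.5.1.1, the version that the submitters' processing notes also name. The intensity values that the authors deposited per spot include a mean signal, a local background and a processed signal, from which the software had subtracted background and spatial trends. The authors also deposited a table of log2 values per probe. Its column medians were 7.08 on each array. Set against the scanner values, the table equalled quantile-normalized log2 processed signals, with a median absolute difference of 0.00231 and a lowest correlation of 0.9999 over arrays. Its scale was thus settled from the values, and its genes were not centred.

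Of 44397 spots on an array, 43020 were not controls. Spots with outlier flags (0.401% over all arrays) were left out, and 0 spots were saturated. The log2 processed signal was averaged over the spots of a probe, giving 39429 probes, and the 75th percentile of each array was subtracted. Probes well above background on at least 3 of the 6 arrays of either group were kept (22446). Probes were named by accession through a gene table of assembly GRCm38.p6, used only for names (28025 probes), then by current symbol (3413) or synonym (295), and 4985 kept the name in the file. The other 2711 had no gene name, 1504 of them among the probes kept, and were not tested as genes. Each gene was taken from its probe with the highest mean over all arrays, giving 16402 genes. Probe positions are those of the array annotation on mm9, which gives no exon or intron.

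The arrays lay on 3 slides, each with 2 arrays of either group and its own scan. In each group 1 sample name stands in the titles of 2 arrays on different slides: replicates 2 and 3 of normal pancreas, and replicates 4 and 6 of tumor. Those arrays were averaged and counted as 1 sample, which left 5 samples per group. Normal replicates 2 and 3 lay on slides 1 and 2, and tumor replicates 4 and 6 on slides 2 and 3. Fits within single slides are therefore not independent of each other. The labels do not say that the names are separate animals, so p-values measure the spread between these samples, which may be partly technical. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over genes, adjusted p under 0.05), with a median of 10.8 degrees of freedom and a median standard error of 0.35 on the log2 scale. The number of arrays limits the precision.

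A gene with no probe well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group over the mean of the dimmer one, in which each array counts with its lowest signal among probes well above background or the probe's own signal, whichever was higher.

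The 38 gene lists hold 532 genes, of which 464 were tested. They cover macrophage identity, resident, monocyte, activation, metabolic and housekeeping programs, and markers of other cells that a sort from pancreas or tumor could hold. The lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists, then with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. The mean of each list per sample was also compared by a two-sided exact permutation test over 252 assignments, whose smallest possible p is 0.00794. Camera passed 15 lists, of which 0 held with an estimated correlation, and fry and the exact permutation test passed 7 each. Lists share genes, such as Ccl17 between chemokines and alternative activation, and Pf4 between chemokines and resident markers. Pdcd1lg2 and Arg1 stand both in alternative activation and in immune suppression and checkpoint.

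The design, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule takes the 12 largest differences in each direction among genes past the threshold whose groups did not overlap and whose symbol is not a clone or locus name, and the 4 members of each list with the smallest p. Some genes that it takes are not reported here. Alternatives covered background correction by normexp (offset 50), quantile and other scalings, the authors' log2 table, the filter on dim probes, the arrays that share a name, the slide, the probes of a gene, outlier flags, the variance model, thresholds, an acinar covariate and leaving out each sample in turn. Scaling on macrophage identity genes, a covariate of S100a8 and S100a9, and the exact permutation test of list means were chosen after seeing the data.

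The fit was tested on simulated data with the means and spreads of the 16402 genes of tumor against normal, 200 of them changed. It recovered 8.96% of genes changed by 1 on the log2 scale, 71.6% of those changed by 2 and 89.4% of those changed by 4, with 7 false calls among 120. With no gene changed, limma made 0 calls over genes and camera 0 over lists in that simulation. Each gene was drawn independently there, whereas genes of real lists vary together, with an estimated correlation of 0.775 for acinar markers. The 0 lists therefore do not show how camera behaves on such lists.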

Results

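Macrophages, phagocytes that reside in tissues or arise there from blood monocytes, were sorted from normal pancreas and from pancreatic tumor tissue of mice labelled as female, C57/B6 and 4 to 5 months old. Each group had 6 arrays, or 5 samples after arrays that share a sample name were averaged. The protocol speaks of implanted tumors, whereas the series design names wild-type mice, KPC mice (a genetic model of pancreatic ductal adenocarcinoma) and a lineage-reporter strain, and the labels do not say which gave each sample. The comparison asks how macrophages of tumor tissue differ in expression from those of the normal organ.

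Between 39.3% and 58.7% of the 39429 probes were well above background on an array, and the 75th percentile of signal ran from 398 to 1547. Normal replicates 2 and 3 were dimmest (398 and 430.2) and normal replicate 6 was brightest. Arrays that share a name correlated at 0.993 and 0.995 across 13227 probes, which are not independent replicates, against at most 0.967 for other pairs of 1 group and 0.957 for pairs of different groups. The first principal component held 26.6% of the variance, with tumor samples from 25.4 to 65.2 and normal samples from -101 to 5.59.

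By the probes tested, Plet1 rose most in tumor samples, and the largest changes of all were falls of digestive-enzyme transcripts. Of 16402 genes, 140 passed an adjusted p under 0.05 in limma, 56 higher and 84 lower in tumor, and 21 of the lower ones were acinar list members. No call was smaller than 1.01 on the log2 scale. The count was 84 without normal replicate 1, 88 without 4 and 59 without 5, and 78 and 71 without tumor replicates 1 and 2. With slide and sample name in the model it was 150. Limma passed 0 genes within slides 1, 2 and 3 and 0 with the acinar list mean as a covariate. At an unadjusted p under 0.05 these fits had 1590, 1565, 953 and 497 genes, against 2126 in the fit that gave the 140. Chance alone would put a share of about 0.05 of the 16402 genes there. The fit with the acinar covariate lay below that share.

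**Figure D1:**
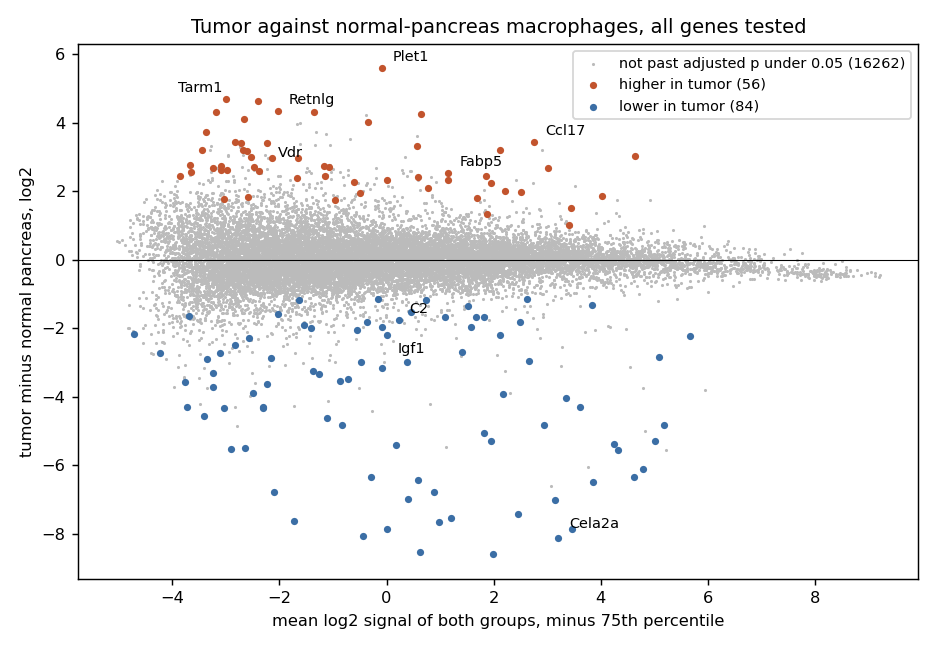
Each point is 1 of the 16402 genes tested, with its mean log2 signal on the x axis and its log2 difference of tumor minus normal pancreas on the y axis (5 samples per group). Colors mark the 56 genes higher and 84 lower in tumor at an adjusted p under 0.05, and the largest falls, such as Cela2a at -8.13, exceed the largest rises, such as Plet1 at 5.59.

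Plet1, a surface protein of placental and other epithelial progenitors, had the largest rise, from -2.89 ± 2.24 to 2.70 ± 1.52 (log2 signal relative to the 75th percentile, SD, 5 samples each), or 48.1-fold (limma adjusted p = 0.0401). Its probe lies on chromosome 9 at 50307294 to 50307353 (mm9). Another probe of Plet1 gave 4.37, and the probe tested was well above background on 4 of 6 normal arrays. The size of the Plet1 rise and its rank are therefore uncertain. Which cells of the sorts gave the Plet1 signal was not tested. Tarm1, an activating receptor of myeloid cells with its probe on chromosome 7 at 3498448 to 3498507 (mm9), was not well above background on any normal array and was at least 5.87-fold higher in tumor (limma adjusted p = 0.00157). Retnlg, a resistin-like protein of neutrophils, rose by 4.34 ± 0.78 (log2, SE), Adra2a, an adrenergic receptor, by 4.32 ± 0.59, and F7, coagulation factor VII, by 4.26 ± 0.46. Vdr, the vitamin D receptor, rose by 3.40 ± 0.64 and Cd300lf, an inhibitory myeloid receptor, by 3.32 ± 0.46. Retnlg was well above background on 2 of 6 normal arrays, and Adra2a and Vdr on 1 each, so the size of these rises is uncertain. Insl6, an insulin-like peptide, and Car6, a carbonic anhydrase, were not well above background on normal arrays and were at least 6.02-fold and 3.21-fold higher. Plet1, Retnlg and Vdr missed the threshold without 7, 7 and 9 of the 10 samples in turn, with highest limma adjusted p of 0.116, 0.0961 and 0.116. With normexp background correction the log2 difference of Insl6 and the log2 difference of Car6 stayed positive but missed the threshold (limma adjusted p = 0.0507 and 0.141). With the S100a8 and S100a9 mean as a covariate 4 of these stayed positive but missed the threshold: the log2 difference of Plet1 was 4.83 (limma adjusted p = 0.231), the log2 difference of Retnlg 3.42 (0.196), the log2 difference of Vdr 2.94 (0.231), and the log2 difference of Cd300lf 3.16 (0.0746). The log2 difference of Car6, which has only a bound, stayed positive there with a limma adjusted p of 0.0746.

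Transcripts of acinar cells, the exocrine cells of the pancreas that make digestive enzymes, were lower in tumor samples throughout. All 26 measured acinar list members had negative differences, with a median of -6.23 (-6.07 with genes below background in a group at their bound), and 21 fell over all genes and 26 adjusted over the list alone. Cela2a, an elastase, fell by 8.13 ± 1.41 (log2, SE), and Rnase1, a ribonuclease, by 8.08 ± 0.81. Klk1, Cela1, Cpb1, Pnliprp1, Pnlip and Cel also fell, with differences of -7.87, -7.86, -7.65, -7.53, -7.44 and -7.02. Rnase1 and Klk1 were well above background on 1 of 6 tumor arrays each, so the size of these falls is uncertain. Pnliprp2, a lipase relative, and Slc38a5, an amino acid transporter outside the list, were not well above background on any tumor array and were at least 29.2-fold and 50.3-fold lower. Pla2g1b, a secreted phospholipase, and Klk1b26, a kallikrein, are also outside the list. Pla2g1b fell by 8.55 ± 1.01 and Klk1b26 fell by 6.98 ± 0.96, and another probe of Pla2g1b gave -2.08.

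Acinar list genes made up 0.665% to 4.14% of the summed signal of tested genes on normal arrays and 0.0115% to 0.286% on tumor arrays. For acinar markers camera's adjusted p was 2.63e-73, but adjusted p = 0.178 with an estimated correlation. Acinar markers had an exact permutation adjusted p of 0.0431 for the mean. The acinar median was -6.23 with slide and sample name in the model, and -8.68, -6.87 and -3.66 for slide 1 alone, slide 2 alone and slide 3 alone. With the list's own mean as a covariate its median was 0.062. Pnliprp1 and Cela2a missed the threshold without 8 and 6 of the 10 samples in turn (highest limma adjusted p 0.115 and 0.0831), and Cel without normal replicate 5 (0.0603). With the S100a8 and S100a9 covariate 5 of these genes stayed negative but missed the threshold: the log2 difference of Cela2a was -6.07 (limma adjusted p = 0.158), the log2 difference of Cela1 -6.11 (0.0523), the log2 difference of Pnliprp1 -5.17 (0.176), the log2 difference of Cel -5.26 (0.0877) and the log2 difference of Klk1b26 -5.55 (0.0523).

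Hormone transcripts of the pancreatic islets were lower in tumor samples too. All 7 measured islet markers were negative, with a median of -1.94 (-0.91 with bounds), 0 past the threshold over all genes and 4 lower adjusted over the list alone. Ins1 and Ins2, which encode insulin, differed by -3.24 ± 0.97 and -3.12 ± 0.84 (log2, SE), Gcg, which encodes glucagon and was well above background on 2 of 6 tumor arrays, by -1.94 ± 0.67, and Ppy, pancreatic polypeptide, by -0.88 ± 0.23. For islet markers camera's adjusted p was 1.20e-04, but adjusted p = 0.267 with an estimated correlation. Islet markers had an exact permutation adjusted p of 0.0431 for the mean. The islet median was -1.92 with slide and sample name in the model. It was -2.73, -2.72 and -0.82 for slide 1 alone, slide 2 alone and slide 3 alone. Slides 1 and 2 both held the sample of normal replicates 2 and 3, so their medians are not independent. The call by camera was lost within slide 2 and also with the acinar covariate (-0.44). Without normal replicates 2 and 3, whose average had an islet list mean of 3.06 against at most 0.76 in other normal samples, the median was -1.12 and the call held.

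Markers of tissue-resident macrophages were lower in tumor, while genes of macrophage identity did not differ by the list test. All 16 resident markers were negative, with a median of -1.67 (-1.55 with bounds), of which 1 fell over all genes and 11 adjusted over the list alone. Igf1, a growth factor, fell from 1.11 ± 0.41 to -1.10 ± 0.21 (log2 signal, SD, 5 samples each), a fall of 4.64-fold (limma adjusted p = 0.00428), with its probe on chromosome 10 at 87393581 to 87393640 (mm9), and its 4 other probes gave -2.31 to -0.46. Cbr2, a carbonyl reductase, Pf4, a chemokine, and Timd4, a receptor for phosphatidylserine, differed by -2.03 ± 0.42, -1.94 ± 0.43 and -3.75 ± 0.85 (log2, SE), short of the threshold over all genes. Timd4 was well above background on 1 of 6 tumor arrays, so its size is uncertain. For resident markers camera's adjusted p was 8.52e-15, but adjusted p = 0.210 with an estimated correlation. Resident markers had an exact permutation adjusted p of 0.0431 for the mean, with all 5 tumor samples below all 5 normal ones. The resident marker median was -1.71 with slide and sample name in the model, and -1.15, -0.74 and -2.24 for slide 1 alone, slide 2 alone and slide 3 alone, and -2.74 with the acinar list mean as a covariate. Macrophage identity had a median of 0.093 over 18 genes and 0 calls over all genes or adjusted over the list alone (camera adjusted p = 0.723), with Adgre1, which encodes F4/80, at -0.80 ± 0.24 and Fcgr3, an Fc receptor, at 0.54 ± 0.22.

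Monocyte markers were higher in tumor. Of 13 members 11 were positive, with a median of 1.43, and 3 rose over all genes and 7 adjusted over the list alone. F10, coagulation factor X, rose by 2.69 ± 0.30 (log2, SE; limma adjusted p = 0.00428) and Hp, haptoglobin, by 3.20 ± 0.43, while Fn1, fibronectin, differed by 0.89 ± 0.20. For monocyte markers camera's adjusted p was 1.92e-13, but adjusted p = 0.175 with an estimated correlation. Monocyte markers had an exact permutation adjusted p of 0.0431 for the mean, with all 5 tumor samples above all 5 normal ones. The monocyte marker median was 1.44 with slide and sample name in the model, and 1.99, 1.08 and 0.97 for slide 1 alone, slide 2 alone and slide 3 alone. With the acinar list mean as a covariate it was 0.78, and camera still passed the list (adjusted p = 0.00304). With the S100a8 and S100a9 covariate the log2 difference of Hp was 2.79, short of the threshold (limma adjusted p = 0.0699).

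**Figure D2:**
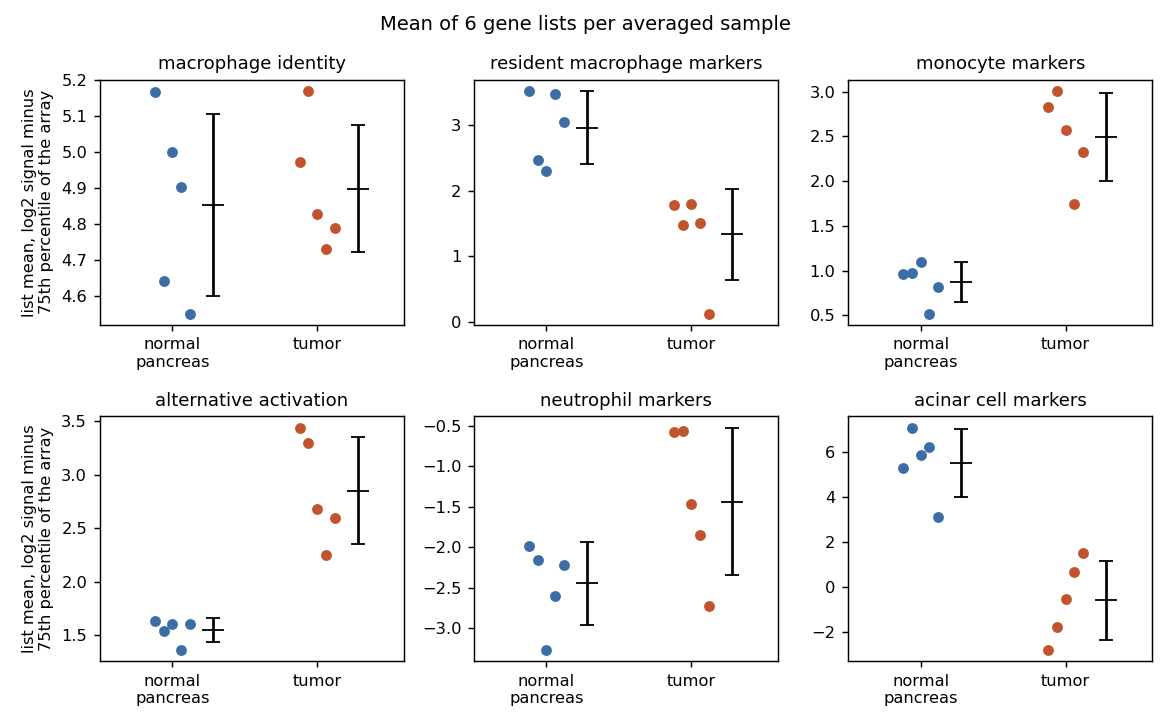
Points are the means of 6 gene lists in each averaged sample, as log2 signal relative to the array's 75th percentile (y axes differ), with the mean and SD of 5 samples beside them. For resident, monocyte, alternative activation and acinar markers all tumor samples lie on 1 side of all normal samples, while macrophage identity and neutrophil markers overlap.

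Genes of alternative activation, the macrophage program that interleukin-4 induces, were higher in tumor. Of 12 members 8 were positive, with a median of 0.89, 2 rose over all genes, and 6 rose and 1 fell adjusted over the list alone. Ccl17, a chemokine that attracts T cells, rose from 1.04 ± 1.22 to 4.48 ± 1.16 (log2 signal, SD, 5 samples each; limma adjusted p = 0.0452). Pdcd1lg2, which encodes the PD-1 ligand PD-L2, was not well above background on any normal array and was at least 4.52-fold higher (limma adjusted p = 0.00599). Arg1, arginase, differed by 3.68 ± 0.79 and Ear2, a ribonuclease, by 1.35 ± 0.34 (log2, SE). Log2 signals of Arg1 ran from -4.35 to -1.15 in normal and from -0.82 to 2.30 in tumor samples, so the size of its difference is uncertain. For alternative activation camera's adjusted p was 1.80e-05, but adjusted p = 0.178 with an estimated correlation. Alternative activation had an exact permutation adjusted p of 0.0431 for the mean. The alternative activation median was 0.87 with slide and sample name in the model, and 0.72, 0.36 and 1.02 for slide 1 alone, slide 2 alone and slide 3 alone. The camera call was lost within slide 2, with the acinar covariate (0.32) and with the S100a8 and S100a9 covariate (0.89). Ccl17 missed the threshold without 8 of the 10 samples in turn (highest limma adjusted p 0.128) and with the S100a8 and S100a9 covariate, where the log2 difference of Ccl17 was 2.97 (0.253). The log2 difference of Pdcd1lg2, which has only a bound, stayed positive but missed it with that covariate (0.0508) and after normexp correction (0.170). Dendritic cell markers, whose test is given with the other cell types, were higher as a list too, with a median of 0.72 (camera adjusted p = 0.0205, but adjusted p = 0.443 with an estimated correlation).

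Immune suppression and checkpoint genes were higher as a list. Of 10 members 8 were positive with a median of 0.49, 1 rose over all genes, which was Pdcd1lg2, and 2 adjusted over the list alone, with Arg1. Lilrb4a, an inhibitory receptor, differed by 0.80 ± 0.40 (log2, SE) and Tgfb1, a cytokine, by 0.42 ± 0.27. For this list camera's adjusted p was 7.26e-04, but adjusted p = 0.267 with an estimated correlation. Suppression genes had an exact permutation adjusted p of 0.0431 for the mean. That mean difference was 0.94, above the median, and includes Arg1 at 3.68 and Pdcd1lg2 at its measured signal, though it has only a bound. Both genes also belong to alternative activation, so the tests of these lists are not independent. The suppression median was 0.46 with slide and sample name in the model, and 0.57, 0.44 and 0.34 for slide 1 alone, slide 2 alone and slide 3 alone. The camera call was lost within slide 2 and with the acinar covariate, where the median turned to -0.022. Of 19 chemokines 13 were negative (median -0.37, camera adjusted p = 0.0560), Ccl17 alone rose over all genes, and 1 rose and 3 fell adjusted over the list alone, with Ccl3 at -1.53 ± 0.40. Chemokines passed camera in 10 of 22 alternatives, thresholds and leaving out samples not counted. One of these took 12 arrays as separate samples (0.0276), which counts arrays of 1 name as independent. With slide and sample name in the model chemokines did not pass. Of 10 chemoattractant receptors 0 passed in limma over all genes or adjusted over the list alone (median 0.31, 0.28 with bounds, camera adjusted p = 0.257), with Ccr7 at 2.41 ± 0.91.

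Antigen presentation, interferon and inflammatory genes did not pass the list test. Medians were 0.016 for 14 genes of MHC class II presentation (-0.00029 with scaling on the median of probes above background on all arrays and -0.030 with scaling on the macrophage identity list), 0.21 for 10 of MHC class I presentation and 0.12 for 15 of the type I interferon response. Camera's adjusted p for these lists were 0.723, 0.391 and 0.499. Inflammatory cytokines and NF-kB targets had a median of -0.20 and a mean of 0.014, which differ in sign (camera adjusted p = 0.583). No member of the 4 lists passed over all genes, and Ccl3 alone passed adjusted over the list alone. Cd40, a costimulatory receptor, differed by 1.20 ± 0.53 (log2, SE), Nlrc5, a regulator of MHC class I genes, by 0.51 ± 0.20, and Usp18, an interferon-induced protease, by 0.63 ± 0.41.

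Metabolic lists were mostly positive in tumor, by small amounts. In hypoxia and glycolysis 20 of 21 members were positive with a median of 0.59, 0 past the threshold over all genes and 3 higher adjusted over the list alone, where the glycolytic enzymes Pgam1, Pfkl and Pfkp differed by 1.05 ± 0.26, 1.01 ± 0.26 and 1.29 ± 0.36 (log2, SE). Another probe of Pfkp gave only 0.16. All 16 cholesterol synthesis genes were positive (median 0.66), 0 past the threshold over all genes and 2 adjusted over the list alone, with Dhcr7 at 0.81 ± 0.22 and Sc5d at 1.44 ± 0.39. In oxidative phosphorylation 19 of 20 were positive (median 0.29) and 0 passed over all genes or adjusted over the list alone, with Sdha at 0.70 ± 0.20 and Cox5a at 0.81 ± 0.24. Of 19 lysosomal genes 13 were positive (median 0.27), 0 past the threshold over all genes and 3 adjusted over the list alone, with the cathepsins Ctsl and Ctsd at 1.23 ± 0.30 and 0.78 ± 0.24.

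For hypoxia and glycolysis camera's adjusted p was 1.80e-05, but adjusted p = 0.345 with an estimated correlation. Hypoxia and glycolysis had an exact permutation adjusted p of 0.0823 for the mean. For cholesterol synthesis camera's adjusted p was 8.90e-05, but adjusted p = 0.345 with an estimated correlation. Cholesterol synthesis had an exact permutation adjusted p of 0.0823 for the mean. For oxidative phosphorylation camera's adjusted p was 6.28e-04, but adjusted p = 0.443 with an estimated correlation. Oxidative phosphorylation had an exact permutation adjusted p of 0.108 for the mean. For lysosomal genes camera's adjusted p was 0.0142, but adjusted p = 0.361 with an estimated correlation. Lysosomal genes had an exact permutation adjusted p of 0.0823 for the mean. Medians with slide and sample name in the model were 0.54, 0.65, 0.28 and 0.29 for glycolysis, cholesterol synthesis, oxidative phosphorylation and lysosome. Within slides 1, 2 and 3 they were 0.45, 0.084 and 0.71 for glycolysis, 0.59, 0.50 and 0.55 for cholesterol synthesis, 0.35, 0.073 and 0.26 for oxidative phosphorylation, and 0.45, 0.26 and 0.25 for lysosome. All 4 camera calls were lost within slide 2, that of oxidative phosphorylation also within slide 3 and that of lysosome within every slide. The calls of cholesterol synthesis (-0.044), oxidative phosphorylation (0.18) and lysosome (0.24) were lost with the acinar covariate, where glycolysis had 0.50 and kept its call. That of lysosome was also lost without normal replicates 2 and 3 (0.11) or 6 (0.20).

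Iron and heme handling genes were lower in tumor as a list. Of 12 members 11 were negative, with a median of -0.36 (-0.31 with bounds), 0 past the threshold over all genes and 3 lower adjusted over the list alone. Tfrc, the transferrin receptor, was not well above background on any tumor array and was at least 1.19-fold lower, short of the threshold over all genes (limma adjusted p = 0.0563), and Cd163, the hemoglobin scavenger receptor, and Hpx, hemopexin, differed by -1.77 ± 0.45 and -1.16 ± 0.35 (log2, SE). For iron and heme handling camera's adjusted p was 0.00149, but adjusted p = 0.178 with an estimated correlation. Iron and heme handling had an exact permutation adjusted p of 0.0431 for the mean. The iron and heme median was -0.37 with slide and sample name in the model, and -0.41, -0.34 and -0.44 for slide 1 alone, slide 2 alone and slide 3 alone, with the camera call lost within slides 1 and 2 and kept with the acinar list mean as a covariate (-0.55). Erythroid markers, given with the other cell types, were lower as a list too, with all 6 negative and a median of -1.74 (camera adjusted p = 0.00302, but adjusted p = 0.267 with an estimated correlation). Of 16 cell cycle genes 14 were positive, with a median of 0.36 (0.27 with bounds) and 0 past the threshold in limma over all genes or adjusted over the list alone, where Aurka and Mcm2 differed by 1.53 ± 0.53 and 0.85 ± 0.34. For cell cycle genes camera's adjusted p was 0.0235, but adjusted p = 0.579 with an estimated correlation. Cell cycle genes had an exact permutation adjusted p of 0.317 for the mean. The cell cycle median was 0.34 with slide and sample name in the model, and 0.066, 0.42 and 0.61 for slide 1 alone, slide 2 alone and slide 3 alone. Its camera call was lost within slides 1 and 2, after normexp correction (0.19), with the stricter filter (0.36), with the acinar covariate (0.47) and without tumor replicate 3 (0.19) or 5 (0.33) or normal replicate 5 (0.016) or 6 (0.32).

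Single members rose or fell in lists that did not pass. Clec4n, the fungal receptor dectin-2, rose by 2.44 ± 0.30 (log2, SE; limma adjusted p = 0.00599) among 13 scavenger and efferocytosis receptors, whose median of 0.085 and mean of -0.36 differ in sign (camera adjusted p = 0.565; 1 higher and 3 lower adjusted over the list alone). Fabp5, a fatty acid binding protein, rose by 2.53 ± 0.32 (limma adjusted p = 0.00599, 0.0523 with the S100a8 and S100a9 covariate, where the log2 difference of Fabp5 was 2.34) among 16 lipid-associated macrophage genes with a median of 0.10 (camera adjusted p = 0.499), the only one adjusted over the list alone. C2, a complement component, fell by 1.76 ± 0.32 (limma adjusted p = 0.0371) and missed the threshold without 8 of the 10 samples in turn (highest 0.111). The 14 complement genes had a median of -0.14 (camera adjusted p = 0.454), with 1 higher adjusted over the list alone, Cfb at 1.08 ± 0.31, and 1 lower. Growth factors had a median of 0.0063 over 12 genes, which turned to -0.0098 with scaling on the median of probes above background on all arrays, -0.039 with scaling on the macrophage identity list and -0.20 after normexp correction (camera adjusted p = 0.376). Igf1 was the only one of them past the threshold over all genes or adjusted over the list alone.

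Matrix remodelling genes had a median of 0.31 over 16 genes (camera adjusted p = 0.0894), 0 past the threshold over all genes, and 4 higher and 1 lower adjusted over the list alone, with Adam8 at 1.27 ± 0.30 and Mmp9 at -2.37 ± 0.61 (log2, SE). Extracellular matrix components had a median of -0.20 (0.0054 with normexp background correction) and a mean of 0.13, which differ in sign (camera adjusted p = 0.565). Of 15 members 0 passed over all genes and 2 were higher adjusted over the list alone, Fn1 and Thbs1 (2.68 ± 0.77). The unfolded protein response had a median of -0.10 (0.031 after normexp correction), with Trib3 at -1.02 ± 0.34. Immediate early and heat shock genes had -0.12 (0.043 after normexp correction), with Jun at -0.75 ± 0.26. Housekeeping genes had a median of -0.041, which turned to 0.16 after normexp correction, 0.073 with quantile normalization and 0.067 in the authors' log2 table, and a mean of 0.088. Camera's adjusted p for the last 3 lists were 0.499, 0.474 and 0.634, and limma passed 0 of their members over all genes or adjusted over the list alone.

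Lists of other cells that the sorts could hold differed in direction. Of 11 neutrophil markers 7 were positive (median 1.18, camera adjusted p = 0.0513), with Retnlg the only call over all genes and 2 higher and 1 lower adjusted over the list alone. The neutrophil list passed camera in other fits, such as with quantile normalization (0.0412). Of 10 dendritic cell markers 8 were positive (median 0.72) with 0 past the threshold in limma over all genes or adjusted over the list alone, among them Itgax at 1.21 ± 0.36 and Dpp4 at 1.71 ± 0.56 (log2, SE). All 6 erythroid markers were negative (median -1.74), 0 past the threshold over all genes and 1 adjusted over the list alone, Epor at -2.72 ± 0.74. Of 11 endothelial markers 8 were negative (median -0.57), 0 past the threshold over all genes and 1 adjusted over the list alone, Robo4 at -3.07 ± 0.79, a size that is uncertain as Robo4 was well above background on 1 of 6 tumor arrays. For dendritic cell markers camera's adjusted p was 0.0205, but adjusted p = 0.443 with an estimated correlation. Dendritic cell markers had an exact permutation adjusted p of 0.177 for the mean. For erythroid markers camera's adjusted p was 0.00302, but adjusted p = 0.267 with an estimated correlation. Erythroid markers had an exact permutation adjusted p of 0.0928 for the mean. For endothelial markers camera's adjusted p was 0.0235, but adjusted p = 0.517 with an estimated correlation. Endothelial markers had an exact permutation adjusted p of 0.328 for the mean.

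Within slides 1, 2 and 3 the medians were 0.62, 0.76 and 0.84 for dendritic cell markers, -2.21, -1.22 and -2.38 for erythroid markers, and -1.11, -1.42 and -0.26 for endothelial markers. With slide and sample name in the model they were 0.74, -1.81 and -0.54. The dendritic camera call was lost within slides 1 and 2, with the mean of a gene's probes (0.66), array weights (0.55) and the acinar covariate (0.56), and without tumor replicate 1 (0.57) or 5 (0.53). The erythroid call was lost within slide 2 and kept with the acinar covariate (-1.51). The endothelial call was lost within slide 3, after normexp correction (-0.41), without the filter on dim probes (-0.65), with array weights (-0.60) or the S100a8 and S100a9 covariate (-0.47), and without normal replicates 2 and 3 (-0.42) or tumor replicates 4 and 6 (-0.73). With the acinar list mean as a covariate endothelial markers passed camera in the other direction, with a median of 1.08 (adjusted p = 0.0382).

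Markers of ductal and tumor epithelium had a median of -0.44 over 15 genes, those of fibroblasts and pericytes -0.12 over 12, T and NK cells -0.27 over 12, and mast cells and eosinophils 0.82 over 7. Camera's adjusted p were 0.376, 0.565, 0.499 and 0.156, and limma passed 0 of their members over all genes or adjusted over the list alone. B cell markers had a median of -0.11, which turned to 0.012 with quantile normalization, 0.0075 in the authors' log2 table and 0.027 after normexp correction, and a mean of 0.17 (camera adjusted p = 0.565). Of 9 members 0 were past the threshold over all genes and 1 higher adjusted over the list alone, Jchain at 1.51 ± 0.44 (log2, SE). Tff2, a trefoil peptide, differed by -2.11 ± 0.75, Des, the muscle filament desmin, by -1.25 ± 0.64, and Cd3e, a T cell receptor component, by -0.50 ± 0.31.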

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

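Apart from the counts over other splits of the samples, the tests of explanations in this part were chosen after the results were seen. A sample stands here where its gap to the nearest other sample of its group was large for the range of the 5 samples. Of 308 groups of samples tested 14 did so, and chance gives about 1 in 20. Values are log2 signals relative to the 75th percentile, each against the range of the other 4 samples of the group.

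Tumor replicate 5 stood apart in Cbr2 (1.85 against 3.54 to 4.22), Pnliprp2 (-4.80 against -5.78 to -5.56), Robo4 (-3.12 against -6.04 to -5.65) and the mean of the resident macrophage list (0.12 against 1.47 to 1.80). Tumor replicate 1 stood apart in Cd3e (-1.02 against -0.069 to 0.12) and Timd4 (-2.99 against -5.99 to -5.61), and the average of tumor replicates 4 and 6 in the mean of oxidative phosphorylation (2.06 against 2.55 to 2.70). The average of normal replicates 2 and 3 stood apart in Hp (1.39 against 0.16 to 0.48), Ncr1 (-3.51 against -1.66 to -1.23), Pdpn (1.54 against -1.17 to -0.53) and the mean of matrix remodelling (0.83 against -0.26 to 0.051). Normal replicate 4 stood apart in Hbb-b1 (-5.57 against -1.38 to -0.74), and normal replicate 6 in Ctsl (-0.036 against 0.71 to 0.97) and the mean of the unfolded protein response (1.13 against 1.74 to 1.87).

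Of 126 splits of the 10 samples into 5 and 5, 100 were drawn. For the 140 genes past the threshold chance is an unlikely cause: only the real split gave as many (1 of 100), and the highest other split gave 12. For the number of lists that camera passed, chance cannot be excluded: 7 of 100 splits gave at least the real 15, and the highest other gave 19. Each of those other splits exchanges 1 tumor sample for 1 normal sample.

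Acinar transcripts were lower in tumor, with a list median of -6.23. The scaling does not account for this, since the median closest to 0 without scaling or under any scaling tried was -5.17, nor does the slide, with -3.66 as the median closest to 0 within a slide. Acinar genes varied together: 98.8% of the variance of acinar genes among normal samples lay on 1 component, against a median of 48.2% and a 95th percentile of 61.4% in 1000 random lists. Mean log2 signals in normal samples were 7.79 for Ctrl, 7.40 for Cela1 and 7.27 for Cela2a, although sorting selects macrophages. Acinar RNA carried into the normal-pancreas sorts and acinar material taken up by macrophages would each give such shared variation. The component was taken among normal samples only, so it cannot bear on a difference between the tissues. All 3 explanations stay open.

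Resident macrophage markers were lower in tumor, with a median of -1.67. A lower share of macrophages in the tumor sorts could lower the macrophage identity list too, and its median was 0.093. Its members moved both ways, however: 10 of 18 were positive and 8 negative, with Adgre1 at -0.80 and Fcgr3 at 0.54. The median therefore cannot exclude a lower share. The slide does not account for the pattern, since the median closest to 0 within a slide was -0.74. A replacement of resident cells by cells derived from monocytes, or a change of expression within resident cells, may be at work, as a hypothesis that these arrays cannot separate.

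Monocyte markers were higher in tumor, with a median of 1.43. Neutrophil RNA in the tumor sorts was tested with the S100a8 and S100a9 mean as a covariate. With this covariate the median was 1.02 and camera's adjusted p 7.29e-10. That p rests on the preset correlation. With an estimated one the list missed the threshold even without the covariate (camera adjusted p = 0.175). S100a8 was not well above background on any normal array, which also weakens the test with the covariate. Whether S100a8 and S100a9 mark neutrophils alone was not tested, so the covariate cannot exclude neutrophil RNA as a cause. Tumor replicate 5 had the lowest neutrophil list mean of its group (-2.73) and a monocyte list mean of 2.32, above all normal samples. The slide does not account for the rise of the monocyte list, with 0.97 as the median closest to 0 within a slide. Entry of monocytes into the tumor is a hypothesis that stays open, untested here.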

How the results depend on the processing

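Scaling on macrophage identity genes, the S100a8 and S100a9 covariate and the exact permutation test of list means were chosen after seeing the data. No paired analysis was possible because the replicate numbers were given in accession order and pair nothing. Dim probes limit what can be measured: 137 genes had only a bound in 1 group that still left a difference. Genes whose bound left no difference are not among the 137 and kept their measured signal in medians with bounds. The 140 called genes kept their sign in every alternative that tested them except the acinar covariate, where 124 did. Among the 140 are 21 acinar list members, whose list mean is that covariate. Over all alternatives, 1243 list medians kept direction and side of the threshold, 47 lost and 56 gained a call and 97 changed sign. For genes these numbers were 3890, 200, 88 and 31.

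Against 140 genes (56 higher, 84 lower), limma passed 214 (98 higher, 116 lower) after normexp correction, 200 (96 higher, 104 lower) with the stricter filter, 460 (228 higher, 232 lower) with 12 arrays as separate samples, 476 (216 higher, 260 lower) with slide as a fixed effect, 236 (117 higher, 119 lower) with a robust variance trend and 203 (90 higher, 113 lower) with array weights. It passed 45 (18 higher, 27 lower) at an adjusted p under 0.01 and 42 (12 higher, 30 lower) with the S100a8 and S100a9 covariate. Counts of 12 arrays treat arrays of 1 name as separate, though their correlation as a random effect was 0.944. Limma gave 2126 genes at an unadjusted p under 0.05 in the fit with 140 calls. Slides 1, 2 and 3 gave 1590, 1565 and 953. Within those slides, where fewer samples remain, limma passed 0 genes in either direction. It also passed 0 with the acinar covariate (497 unadjusted), which correlates with the group at -0.902 and raises the median standard error from 0.35 to 0.81. There Igf1 went from -2.21 ± 0.24 to -2.02 ± 0.58 and Ccl17 from 3.44 ± 0.67 to 0.80 ± 1.33 (log2, SE). Leaving out a sample or array gave 59 to 197 genes, 26 to 79 higher and 33 to 118 lower, and 14 to 17 lists. Against 15 lists, 7 passed within slide 2, 0 by camera with an estimated correlation, 7 by fry and 7 by the exact permutation test of list means.

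With normexp background correction list medians turned to the other sign for extracellular matrix components 0.0054, growth factors -0.20, unfolded protein response 0.031, immediate early and heat shock 0.043, housekeeping 0.16 and B cell markers 0.027. With normexp background correction gene differences turned for Il23a -0.061. With quantile normalization list medians turned to the other sign for housekeeping 0.073 and B cell markers 0.012. With scaling on the median of probes above background on all arrays list medians turned to the other sign for MHC class II presentation -0.00029 and growth factors -0.0098. In the authors' log2 table list medians turned to the other sign for housekeeping 0.067 and B cell markers 0.0075. With no filter on dim probes list medians turned to the other sign for growth factors -0.28, mast cell and eosinophil markers -0.28 and sex-linked check -0.48. With only probes above background on all arrays of a group list medians turned to the other sign for unfolded protein response 0.065. With 12 arrays as separate samples list medians turned to the other sign for matrix remodelling -0.15, growth factors -0.021, scavenger and efferocytosis receptors -0.019 and B cell markers 0.021. With 12 arrays as separate samples gene differences turned for Xist -0.64. With 12 arrays and slide as a fixed effect list medians turned to the other sign for matrix remodelling -0.15, growth factors -0.021, scavenger and efferocytosis receptors -0.019 and B cell markers 0.021. With 12 arrays and slide as a fixed effect gene differences turned for Xist -0.64. For slide 1 alone list medians turned to the other sign for matrix remodelling -0.13, B cell markers 0.041 and sex-linked check -1.23. For slide 1 alone gene differences turned for Top2a -0.13 and Xist -5.10. For slide 2 alone list medians turned to the other sign for macrophage identity -0.027, MHC class II presentation -0.28, MHC class I presentation -0.18, type I interferon response -0.26, matrix remodelling -0.26, growth factors -0.27 and lipid-associated macrophage -0.43. For slide 2 alone gene differences turned for Psmb9 -0.084. For slide 3 alone list medians turned to the other sign for inflammatory cytokines and NF-kB targets 0.13, extracellular matrix components 0.47, growth factors -0.17, scavenger and efferocytosis receptors -0.53, immediate early and heat shock 0.036, housekeeping 0.15, ductal and tumor epithelial markers 0.41 and fibroblast and pericyte markers 0.55. For slide 3 alone list medians turned to the other sign for B cell markers 0.23. With array quality weights list medians turned to the other sign for MHC class II presentation -0.072, extracellular matrix components 0.031, growth factors -0.029, housekeeping 0.048 and fibroblast and pericyte markers 0.10. With the acinar covariate list medians turned to the other sign for immune suppression and checkpoint -0.022, chemoattractant receptors -0.46, extracellular matrix components 1.01, lipid-associated macrophage -0.19, cholesterol synthesis -0.044, scavenger and efferocytosis receptors -0.84, unfolded protein response 0.25 and housekeeping 0.31. With the acinar covariate list medians turned to the other sign for acinar cell markers 0.062, ductal and tumor epithelial markers 1.01, fibroblast and pericyte markers 1.26, endothelial markers 1.08, neutrophil markers -0.84 and B cell markers 0.50. With the acinar covariate gene differences turned for Asns 0.11, Cd3e 0.10, Cd40 -0.48, Cel 0.50, Cela2a 0.80, Cfb -0.033, Cldn7 0.46 and Egfl7 1.58. With the acinar covariate gene differences turned for Eif2s3y -0.32, H2-Oa -0.23, Hpx 0.63, Idi1 -0.029, Lilrb4a -1.14, Pnliprp1 1.83, Robo4 0.87 and Tek 0.74. With the acinar covariate gene differences turned for Tff2 1.29, Tgfb1 -0.29, Trib3 0.26 and Usp18 -0.40. With scaling on the macrophage identity list list medians turned to the other sign for MHC class II presentation -0.030 and growth factors -0.039. With the S100a8 and S100a9 covariate list medians turned to the other sign for macrophage identity -0.049, MHC class II presentation -0.047, inflammatory cytokines and NF-kB targets 0.12, extracellular matrix components 0.14, scavenger and efferocytosis receptors -0.25, immediate early and heat shock 0.043, housekeeping 0.086 and ductal and tumor epithelial markers 0.13. With the S100a8 and S100a9 covariate list medians turned to the other sign for fibroblast and pericyte markers 0.16 and B cell markers 0.069. When a sample or array was left out, values ran from -0.79 to 1.12 for Xist, -0.40 to 0.035 for B cell markers, -0.16 to 0.19 for MHC class II presentation, -0.41 to 0.11 for extracellular matrix components, -0.34 to 0.21 for fibroblast and pericyte markers, -0.15 to 0.11 for growth factors, -0.11 to 0.048 for housekeeping, -0.39 to 0.036 for inflammatory cytokines and NF-kB targets, -0.0091 to 0.94 for matrix remodelling and -0.043 to 0.23 for scavenger and efferocytosis receptors. Il23a and Top2a were not well above background on any normal array, so their signs are uncertain. The acinar covariate is the mean of the acinar list itself. With it, that list and its members Cel, Cela2a and Pnliprp1 must scatter around 0, so their signs there carry no information. The cause was not tested for Il23a, Top2a or the other changes above.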

Other observations

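All samples are labelled female. Xist, the transcript of the inactive X chromosome, had log2 signals relative to the 75th percentile of 0.77, -0.42, -4.51, -4.92 and -5.24 in normal samples (replicates 1, 2 with 3, 4, 5 and 6) and -5.29, -4.46, 1.35, -5.31 and 0.45 in tumor samples (replicates 1, 2, 3, 4 with 6, and 5). Eif2s3y, a gene of the Y chromosome, had -4.32, -3.69, -0.78, -2.17 and -0.99 in normal and -0.98, -1.75, 1.15, -0.033 and -2.96 in tumor samples, in the same order. Xist was well above background on 3 normal and 2 tumor arrays, and Eif2s3y on 3 and 6. The list of sex-linked genes had 2 measured members, a median difference of 0.85 and a camera adjusted p of 0.528. Those members, Xist and Eif2s3y, mark opposite sexes, so their joint median and p can hide a difference in sex between the groups. Signal of a Y chromosome gene is at odds with the female label. So is Xist at -4.46 or below in normal replicates 4, 5 and 6 and tumor replicates 1, 2 and 4 with 6. Tumor replicate 3 was highest in both genes, at 1.35 and 1.15. The sex of the samples was not settled here.

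Among genes that the rule takes, 2 had another probe of the other sign. Cycs, a gene of oxidative phosphorylation, was at 0.62 for the brightest probe and -0.16 for another.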
